A study of Homo sapiens with 6 samples.

How the data were processed

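Gene expression was measured on Affymetrix whole-transcript arrays, with 1 array for each of 6 cultures of the human breast carcinoma cell line HS578T. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and labelled with the GeneChip WT PLUS reagents. The deposited table holds 1 value per probe set (transcript cluster) and array, for 21448 probe sets. Per the submitters' processing notes the authors used Partek 6.6. The background correction, normalization, summarisation and genome build are not given in the sources used here.

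The authors' deposited values were taken as log2 values. That scale was inferred from the values, since no label states it. They ran from 1.787 to a ceiling of 19.93, which is log2 of 999973. The 6 array medians lay between 4.456 and 4.497, and no gene centring was seen, so the columns appeared to share a normalization. A total of 15 probe sets sat at the ceiling on all 6 arrays. Together with 4 probe sets below the ceiling, 19 had the same value on all arrays within a tolerance of 0.001. The 15 are taken as saturated. Why the other 4 (levels from 13.06 to 19.62) did not vary was not tested. None of the 19 gives information on a difference. A further 2 probe sets (TGFBI and SPARC, named after their values were seen) were at the ceiling on some arrays but not all, which caps their values there. The table holds neither detection calls nor signals over background, so probe sets below background could not be set apart. The number of arrays limits the precision.

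Probe sets were named from the platform's annotation. It gave 1 gene symbol for 17709 probe sets, several for 0, and listed none for the other 3739 (17.4%), which stayed in the tests without a name. The gene identifiers of all 17709 named probe sets were found in a RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. That table served only for names, gene order and chromosome. No coordinates are given, because the build of the array annotation is not stated.

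The comparison was EP300 arrays minus control arrays, 3 against 3. It was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited values, with no filter, no covariate and no block. Benjamini-Hochberg adjustment was made over all 21448 probe sets, with a threshold of 0.05. Errors of single groups are SD over 3 cultures. Errors of differences are limma's moderated standard errors or 95% intervals. The series' design text describes independent cultures of stably transfected pools, and does not say whether the cultures of a condition came from 1 pool. The p-values therefore measure the spread between cultures, and whether this includes a spread between independent transfections is unknown.

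A set of 35 gene lists was fixed before the data were examined, with 993 distinct genes, of which 886 were measured. For list tests each of 17687 genes was represented by its probe set with the highest mean over all arrays. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and with Benjamini-Hochberg adjustment over the 35 lists. Camera with an estimated correlation (4 residual degrees of freedom) and fry, which asks whether a list's genes change without comparing them with other genes, were run beside it.

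The genes named in the text follow a rule fixed at the same time. It takes EP300 and its paralog CREBBP, then, among protein-coding genes past the threshold whose groups do not overlap, up to 12 with the largest change in each direction. If none pass, as was the case, it takes the 5 with the smallest p in each direction. It adds the 4 members of each called list with the smallest p in the list's direction, and the 3 with the smallest p of each of 6 fixed lists (epithelial, mesenchymal, EMT transcription factors, interferon-stimulated, ABC transporters and p53 targets). It named 39 distinct genes. Genes outside it, AKR1C2 among them, are said to be chosen after their values were seen. Members of families with close sequences (AKR1C, metallothioneins, histones) are uncertain, because their probe sets can take up each other's signal.

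Simulated data had the real means of the 21448 probe sets and variances drawn from limma's fitted prior, so they follow that model. The fit was tested on 20 simulations of the same comparison, with 200 probe sets changed. At an adjusted p of 0.05 it recovered 11.4% of changes of 1 on the log2 scale, 88.7% of changes of 2 and 98.9% of changes of 3, and 4.58% of the calls were false. In 20 simulations on 17687 genes, a list of 31 genes shifted by -0.25 was called by camera in 15. Of 680 tests of unshifted lists, 2 were called. Genes were drawn independently of each other, so these counts do not cover lists whose members are correlated.

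Alternatives fixed before the data were examined were quantile normalization, median centring, the probe sets above the median level, 1 probe set per gene, a variance trend with robust estimation (for single probe sets), array weights, the replicate number as a block, leaving out each array, a 1.5-fold minimum, an adjusted p of 0.01, an estimated correlation, and the mean over the probe sets of a gene. For lists the trend was used without robust estimation, which camera does not offer, and counts as added after seeing the data. Leaving out the constant probe sets and leaving out list members shared between called lists were added after seeing the data, as was the count of probe sets at an unadjusted p below 0.05. The planned check of the EP300 level was not carried out, because no probe set carries that symbol in the annotation used here.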

Results

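Transcript levels were compared between HS578T cells that carried an EP300 expression vector and cells that carried the empty vector pcDNA 3. HS578T is a human breast carcinoma line of mesenchymal appearance, and EP300 encodes a lysine acetyltransferase that acts as a transcriptional co-activator. Stable transfectants had been selected with G418 and pooled. Each condition was represented by 3 cultures, each hybridised to its own array. The comparison addressed which transcripts differ between cells with the EP300 vector and cells with the empty vector.

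The 6 arrays had similar value distributions, with medians from 4.456 to 4.497 on the log2 scale. Pearson correlations over all probe sets were 0.9786 to 0.9807 within the control group, 0.9784 to 0.9802 within the EP300 group and 0.977 to 0.9807 between the groups, so pairs from different groups were about as alike as pairs from the same group. The first principal component held 23.1% of the variance. It placed the control arrays at -33, -18.6 and -13.5, and the EP300 arrays at 6.9, 27 and 31.3. A random order of the arrays separates 3 from 3 in 10% of cases. The second component held nearly as much (20.9%) and set EP300 replicates 2 and 3 apart, at -41.3 and 35.2, with the other arrays between -6.17 and 7.52.

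The level of EP300 itself, which would check the labels, was not analysed here, because none of the named probe sets carries that symbol. Its paralog CREBBP, a second acetyltransferase co-activator, measured 9.81 ± 0.33 in control and 10.07 ± 0.54 in EP300 cultures (log2, mean ± SD, n = 3 each). The difference of 0.26 had a 95% interval from -0.42 to 0.94 and a limma adjusted p of 0.915 (0.844 to 0.991 over the alternative settings), and without 1 array it ran from -0.0517 (EP300 replicate 3) to 0.446 (control replicate 3).

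No single gene passed the threshold. The genes with the smallest p in the upward direction were AKR1C1, AKR1C3, CDH6, RPS27L and MEF2C. AKR1C1 and AKR1C3 encode aldo-keto reductases that act on steroids and other carbonyl compounds. The AKR1C1 probe set read 8.48 ± 0.26 in control and 10.74 ± 0.50 in EP300 cultures, which is 4.8-fold (log2 difference 2.26 ± 0.29 SE, limma adjusted p = 0.222). AKR1C3 was 2.87-fold higher (1.52 ± 0.24, limma adjusted p = 0.407). AKR1C2, chosen after its values were seen, was 3.11-fold higher (1.64 ± 0.30, limma adjusted p = 0.447). These transcripts are close in sequence, and signal shared between their probe sets was not separated from their own. CDH6, which encodes a cadherin, was 2.96-fold higher and RPS27L, a ribosomal protein paralog, 2.26-fold. The transcription factor gene MEF2C read 3.29 ± 0.26 in control and 4.79 ± 0.40 in EP300 cultures. Its control level lay below the lower quartile of each array (3.468 to 3.495), where the background is unknown, so no fold is given. The limma adjusted p of these 3 genes lay between 0.407 and 0.436.

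In the downward direction the 5 genes were SMG8, MXI1, IGFBP3, BGN and SCD. SMG8, a regulator of the nonsense-mediated decay kinase, read 4.45 ± 0.10 in control and 3.09 ± 0.21 in EP300 cultures, the latter also below the lower quartile of each array. MXI1, which encodes a MAX partner that opposes MYC, was 2.58-fold lower. IGFBP3, which encodes an insulin-like growth factor binding protein, read 14.58 ± 0.30 in control and 13.30 ± 0.09 in EP300 cultures, a 2.42-fold difference. BGN, which encodes the matrix proteoglycan biglycan, was 2.65-fold lower. SCD, which encodes stearoyl-CoA desaturase, read 13.56 ± 0.01 in control and 12.42 ± 0.22 in EP300 cultures, a 2.19-fold difference. The limma adjusted p of these 5 genes lay between 0.407 and 0.476. For each of the 10 genes the 3 EP300 arrays lay on one side of the 3 control arrays. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Because the genes were chosen by their small p, this separation is no further evidence.

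**Figure D1:**
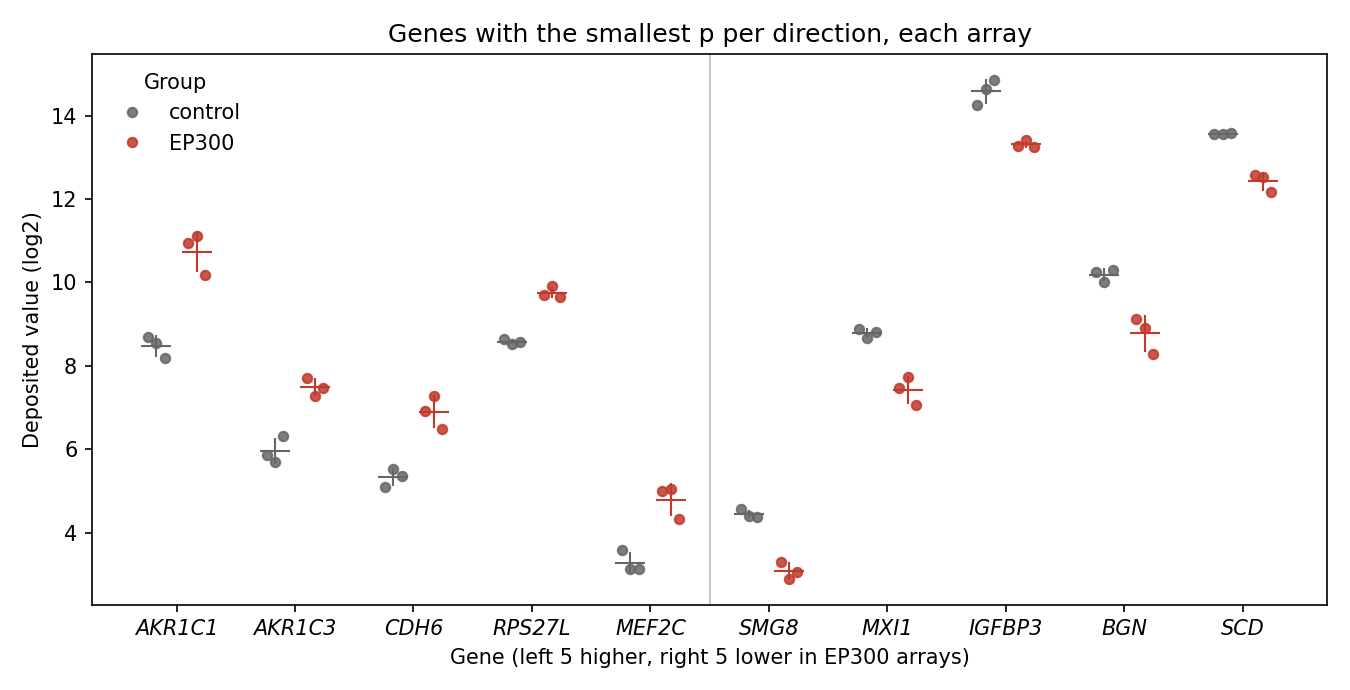
Deposited log2 value (vertical axis) of the 5 genes with the smallest p in each direction (horizontal axis), with 1 point per array, a horizontal line at the group mean and a vertical bar of 1 SD (n = 3 per group). The groups do not overlap for any of the 10 genes, and AKR1C1 shows the widest gap, with means of 8.48 and 10.74.

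Over all probe sets, limma called 0 of 21448 at an adjusted p of 0.05, and the lowest adjusted p was 0.222. At an unadjusted p below 0.05 it counted 1399 probe sets, 741 higher and 658 lower in EP300 cultures, where 1072.4 would be counted by chance. The groups did not overlap for 2618 probe sets (12.2%), against a chance share of 10%. The median absolute difference was 0.2 on the log2 scale, and 113 probe sets differed by more than 1, of which 77 were higher and 36 lower. With a variance trend and robust estimation in place of a constant prior, 4 genes passed: AKR1C1, which was higher (limma adjusted p = 0.02), and IGFBP3 (0.034), TAGLN (0.034) and SCD (0.0435), which were lower. Over all alternative settings the adjusted p reached up to 0.855 for AKR1C1 and 0.866 for the other genes. Probe sets without a listed gene were also among those with the smallest p.

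Among the 35 fixed gene lists, 4 lay lower than the other genes by camera at the preset correlation, and 0 lay higher. These 4 were hypoxia response genes, mesenchymal markers, collagens with fibrillar matrix genes, and metallothioneins. With a variance trend 6 lists passed, the same 4 and cholesterol and lipid synthesis as lower, and the ribosomal proteins as higher. With an estimated correlation 0 of the 35 lists passed, and 2 had an unadjusted camera p below 0.05. By limma no member of any list passed the adjustment over all probe sets, while 17 passed when adjusted over the list alone, counting a gene once in each list that holds it.

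Of 31 measured hypoxia response genes, 23 were lower and 8 higher in EP300 cultures, with a median log2 difference of -0.19 (camera adjusted p = 5.14e-04, and adjusted p = 0.329 with an estimated correlation, the highest of all settings). Adjusted over the list alone, 2 members passed, both lower: MXI1 at -1.37 ± 0.24 SE (0.0063) and PDK1 at -0.93 ± 0.21 (0.0234). PDK1 encodes a pyruvate dehydrogenase kinase. LOX, encoding lysyl oxidase, differed by -0.67 ± 0.21, and the glucose transporter gene SLC2A1 by -0.69 ± 0.23, and neither passed. The glycolysis list, which shares SLC2A1 and other members with the hypoxia list, had a median of -0.06 over 19 genes. It did not pass (camera adjusted p = 0.416) and is no independent check. At an unadjusted limma p below 0.05, 3 of its members were lower and 0 higher.

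Of 26 measured mesenchymal markers, 19 were lower and 6 higher, with a median log2 difference of -0.24 (camera adjusted p = 0.0017). With an estimated correlation the camera adjusted p was 0.329, the highest of all settings. The estimate itself was 0.00341, below the preset 0.01. Adjusted over the list alone, 3 members passed, all lower: TAGLN at -1.18 ± 0.22 SE (0.00982), ACTA2 at -0.80 ± 0.20 (0.0323) and THY1 at -0.75 ± 0.20 (0.0401). TAGLN and ACTA2 encode transgelin and smooth muscle actin, proteins of the contractile cytoskeleton, and THY1 encodes a surface glycoprotein of fibroblasts. VIM, encoding vimentin, had the same value of 18.6 on all 6 arrays, below the ceiling of the array values, and gave no information on a difference, and SPARC was capped at the ceiling on some arrays.

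Of 30 collagen and fibrillar matrix genes, 20 were lower, with a median of -0.16 (camera adjusted p = 0.0209, and adjusted p = 0.567 with an estimated correlation). The list shares DCN, FBN1, FN1, LUM and SPARC with the mesenchymal markers, and without members shared between called lists the median was -0.155 over the 25 genes left, close to the -0.156 over all 30, while the list no longer passed (camera adjusted p = 0.0681). BGN was the 1 member to pass when adjusted over the list alone, at -1.41 ± 0.26 SE (0.00987). COL5A1 differed by -0.78 ± 0.23, DCN by -0.73 ± 0.31 and COL1A2 by -0.49 ± 0.22. The call was lost without control replicate 3 (median -0.117, camera adjusted p = 0.184) and without EP300 replicate 1 (-0.142, 0.291), and held without EP300 replicate 3, where the median was smaller (-0.0925, 0.0238). Over all settings the adjusted p ran from 6.45e-04 to 0.567.

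Metallothioneins, small metal-binding proteins, had a median of -0.29 over 10 genes, of which 9 were lower and MT2A was saturated (camera adjusted p = 0.0249, and adjusted p = 0.6 with an estimated correlation). By limma 0 members passed when adjusted over the list alone, and 0 had an unadjusted p below 0.05. MT1B differed by -0.50 ± 0.26 SE, MT1H by -0.45 ± 0.25, MT1X by -0.43 ± 0.27 and MT4 by -0.46 ± 0.29. Without control replicate 1 MT1X was at -0.19 and MT4 at -0.285, without control replicate 3 MT1H was at -0.68, MT1X at -0.69 and MT4 at -0.69, and without EP300 replicate 3 MT4 was at -0.26. The MT1 genes are close in sequence, and the estimated inter-gene correlation of the list was 0.508. MT4 read 4.15 in control and 3.69 in EP300 cultures, below the median of each array (4.456 to 4.497). The call was lost without control replicate 1 (median -0.12, camera adjusted p = 0.584), control replicate 2 (-0.27, 0.183), EP300 replicate 1 (-0.28, 0.149) or EP300 replicate 3 (-0.29, 0.148). Without control replicate 3 the median was -0.58 and the adjusted p 3.42e-05, so that over all settings it ran from that value to 0.6.

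**Figure D2:**
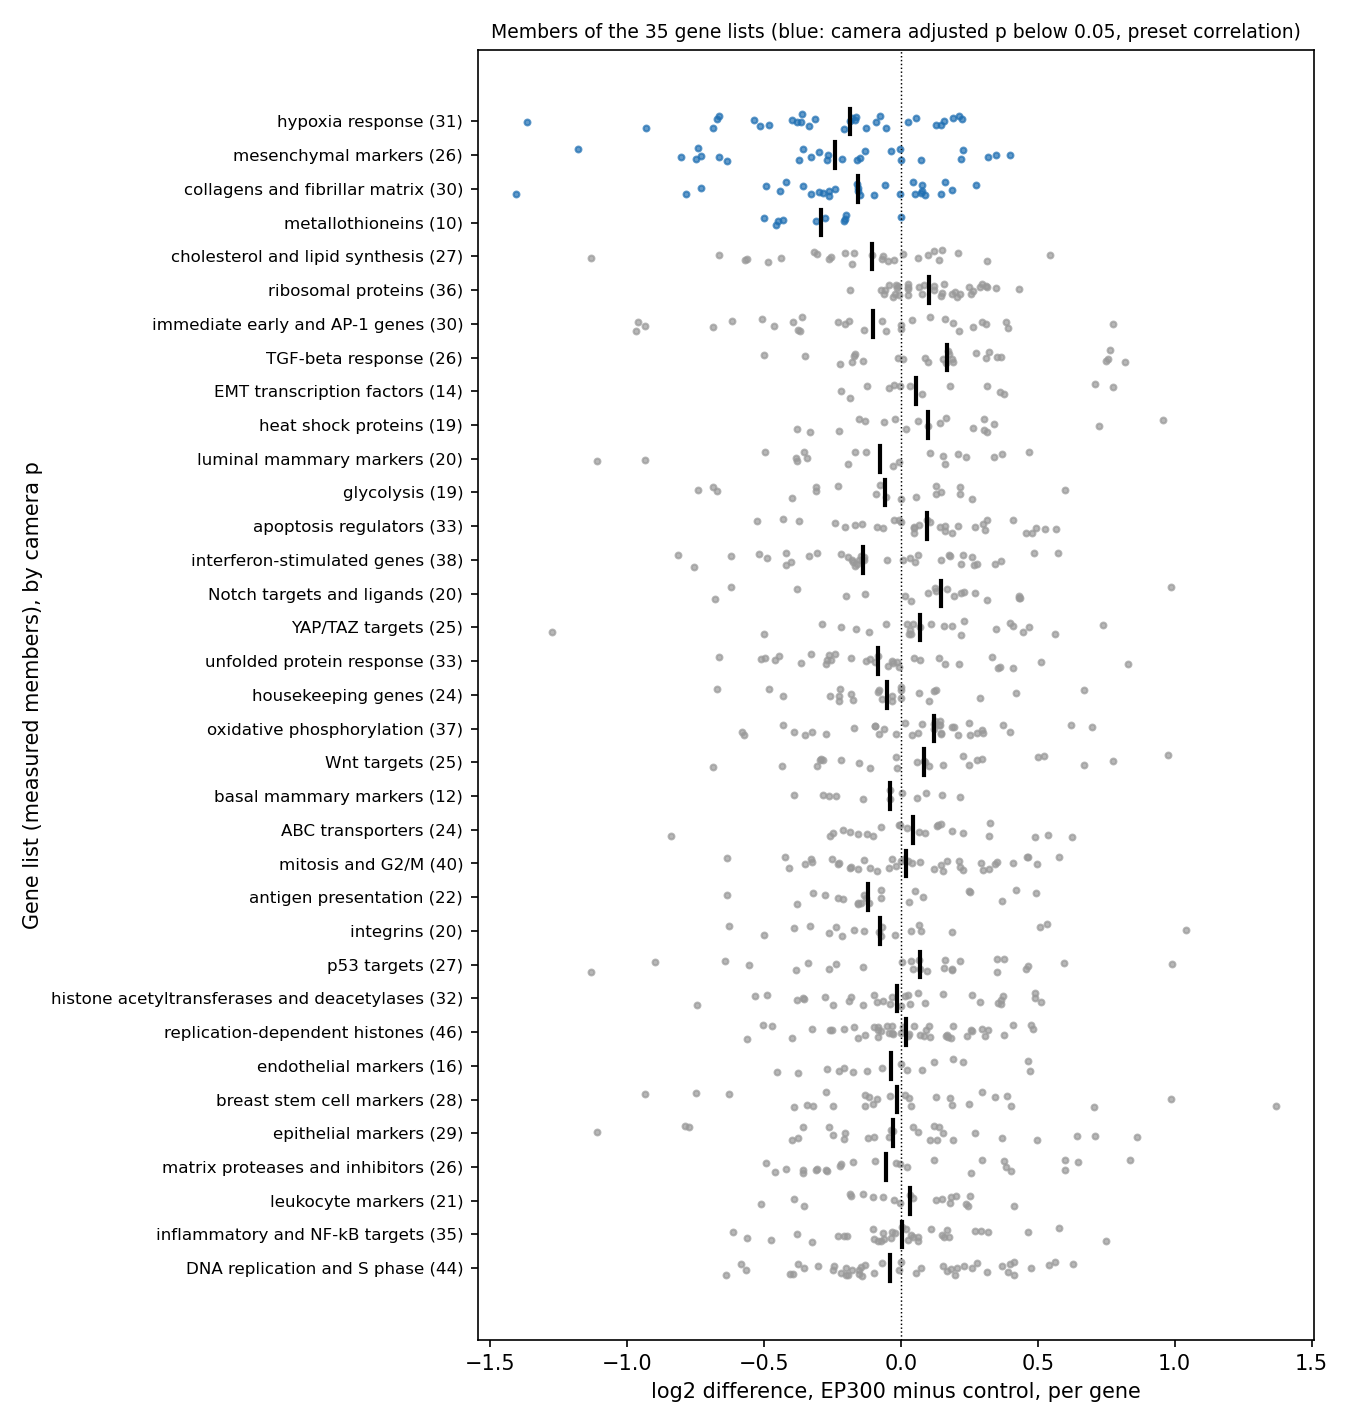
Log2 difference between EP300 and control cultures (horizontal axis) of each measured member of the 35 gene lists (vertical axis, ordered by camera p), with 1 point per gene and a black bar at the list's median. The 4 lists in blue, called at the preset correlation, have medians from -0.16 to -0.29, and the other medians lie between -0.14 and 0.17.

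Epithelial markers did not pass as a list (29 genes, median -0.03, camera adjusted p = 0.951). The median level of the list was 3.66, near the lower quartile of the arrays (3.468 to 3.495), and 10 members lay above the median level. Such low levels, where the background is unknown, limit what this result shows. KRT18, encoding a keratin of simple epithelia, was 2.16-fold lower at -1.11 ± 0.23 SE and was the 1 member to pass when adjusted over the list alone (0.0222). The junction genes TJP1 and JUP differed by 0.64 ± 0.21 and 0.86 ± 0.30 and did not pass, and JUP was at 0.56 without EP300 replicate 3. EMT transcription factors had a median of 0.05 over 14 genes (camera adjusted p = 0.301). SNAI2 read 16.54 ± 0.25 in control and 17.25 ± 0.22 in EP300 cultures, LEF1 differed by 0.78 ± 0.27 and GSC by 0.38 ± 0.26, and none passed within the list. GSC lay below the lower quartile of the arrays in both groups and was at 0.19 without EP300 replicate 3.

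Interferon-stimulated genes had a median of -0.14 over 38 genes (camera adjusted p = 0.416). IRF9 and BST2 differed by -0.81 ± 0.22 SE and -0.76 ± 0.22, and IFIT5 by 0.57 ± 0.24 (0.38 without EP300 replicate 3). ABC transporters had a median of 0.04 over 24 genes (camera adjusted p = 0.807), with ABCB10 at -0.84 ± 0.27, ABCB6 at 0.62 ± 0.22 and ABCC2 at 0.49 ± 0.24 (0.28 without EP300 replicate 2). Targets of p53 had a median of 0.07 over 27 genes (camera adjusted p = 0.88), with TP53INP1 at -1.13 ± 0.27, TP53I3 at 0.99 ± 0.33 and AEN at -0.90 ± 0.33. TP53I3 was at 0.65 without control replicate 3 and AEN at -0.50 without EP300 replicate 2. ABCC2 in both groups and BST2 in the EP300 group had means below the lower quartile of the arrays. The median level was 3.92 for the interferon-stimulated list, 3.96 for the ABC transporters and 5.87 for the targets of p53. The former and the ABC transporters thus lay below the array medians (4.456 to 4.497), which limits what their results show. By limma 0 members of these 3 lists passed when adjusted over the list alone. At an unadjusted p below 0.05 there were 3 interferon-stimulated genes, 2 ABC transporters and 5 targets of p53.

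Breast stem cell markers went both ways. The median was -0.01 over 28 genes while the mean was 0.03, and the list did not pass (camera adjusted p = 0.942). Adjusted over the list alone, 5 members passed, which are named here after their values were seen. The Notch target HES1 was higher by 0.99 ± 0.22 SE, the aldehyde dehydrogenase gene ALDH1A1 by 1.37 ± 0.36 and the surface marker CD24 by 0.71 ± 0.21, and THY1 (-0.75) and the transcription factor gene KLF4 (-0.93 ± 0.27) were lower.

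Cholesterol and lipid synthesis genes had a median of -0.11 over 27 genes, of which SCD was the 1 to pass when adjusted over the list alone (0.00933), and the list did not pass (camera adjusted p = 0.0973). It passed, as lower, with quantile normalization (0.0494), among probe sets above the median level (0.0421), with a variance trend (0.037), without control replicate 1 (0.019) and without EP300 replicate 2 (0.0434). It did not pass with an estimated correlation (0.567) or in any other setting, and lay further from the threshold without control replicate 3 (0.305) and without EP300 replicate 1 (0.362). Ribosomal proteins had a median of 0.10 over 36 genes and did not pass (0.116), but passed as higher with a variance trend (4.63e-04), and in no other setting (0.567 with an estimated correlation). TGF-beta response genes had a median of 0.17 over 26 genes (0.144) and immediate early genes of -0.10 over 30 (0.116), and neither list passed.

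Proliferation lists did not pass, with medians of 0.02 over 40 mitosis genes and -0.04 over 44 DNA replication genes (camera adjusted p = 0.834 and 0.994). Histone acetyltransferases and deacetylases had a median of -0.02 over 32 genes (0.922), inflammatory and NF-kB targets of 0.00197 over 35 (0.994), and housekeeping genes of -0.05 over 24 (0.64). For DNA replication genes the mean was 0.00663 and camera's direction higher, against the negative median. For the inflammatory targets camera's direction was lower with a mean of 0.00334, and for 26 matrix proteases and inhibitors it was lower with a median of -0.06 and a mean of 0.02 (0.964). Markers of cell types that the cultures should lack did not pass either, with medians of 0.03 for 21 leukocyte and -0.03 for 16 endothelial markers (camera adjusted p = 0.964 and 0.922). The median levels of these 2 lists were low (3.79 and 3.73), where the background is unknown, which limits what they show. Luminal mammary markers had a median of -0.08 over 20 genes (0.366) and basal ones of -0.04 over 12 (0.72). Among probe sets above the median level, where 8 luminal markers were left, the luminal list passed as lower (camera adjusted p = 0.041), and in no other setting (0.567 for all 20 with an estimated correlation). In the luminal list KRT18 and the mucin gene MUC1 (-0.93 ± 0.22 SE, named after its value was seen) passed when adjusted over the list alone.

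The fry test for change in either direction passed for 16 of the 35 lists, among them the epithelial markers and the YAP/TAZ targets (both adjusted p = 5.53e-06). In the YAP/TAZ list IGFBP3 (-1.28) stood beside the tissue factor gene F3 (0.74 ± 0.25 SE), which is named here after its value was seen. The fry test for change in 1 direction passed for 0 lists, with 6 at an unadjusted p below 0.05. Its adjusted p was 0.133 for the hypoxia list and 0.0563 for the mesenchymal list.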

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

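The count of probe sets at an unadjusted p below 0.05 and the settings without constant probe sets, without shared list members and, for lists, with a variance trend alone were chosen after seeing the data. The count of 0 probe sets past the threshold held under every setting run but 1: with a variance trend and robust estimation 4 passed, and the cause was not tested. The count at an unadjusted p below 0.05 was 848 among the 10724 probe sets above the median level and 1136 with 1 probe set per gene, both with fewer tests, 1225 to 1383 without 1 array, and 1373 to 1455 under the other settings without a block. No shared effect of the replicate number was seen: the deviations of same-numbered cultures correlated at -0.00893 to -0.00153, and no culture correlated best with its own number. Whether same-numbered cultures were handled together is not stated. With the number as a block 0 probe sets passed, 1295 had an unadjusted p below 0.05, and the same 4 lists were called. With an estimated correlation, a test on 4 residual degrees of freedom, the called lists went from 4 to 0. The estimate was 0.00341 for the mesenchymal list, below the preset 0.01. A higher correlation is thus argued against as what ended that call. It was 0.0225 for the hypoxia list, 0.117 for the collagens and 0.508 for the metallothioneins, and the cause was not tested there. The count of called lists was 6 among probe sets above the median level (all lower) and 6 with a variance trend (5 lower, 1 higher). It was 5 with quantile normalization and 3 without shared members. The added lists were cholesterol synthesis in the first 3 of these, luminal markers in the first and ribosomal proteins in the second. Without 1 array 2 to 5 lists were called, the 2 without EP300 replicate 1 being the hypoxia and mesenchymal lists. Those lists passed in every setting run except the estimated correlation, with medians from -0.26 to -0.17 and from -0.28 to -0.16. Scaling moved the median of all probe sets by under 0.1. Of 513 recomputed differences of the named genes 508 kept their direction and side of the threshold, 4 passed with a variance trend and robust estimation together, and 1 reversed: CREBBP was at -0.0517 without EP300 replicate 3, and at up to 0.45 without another array. No value could be recomputed for EP300. No difference can be read from 19 probe sets, 15 of them at the ceiling, and the ceiling can shorten the differences of 2 others that reach it on some arrays, and without detection calls the signal over background is unknown.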

Other observations

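The NRF2, SRF and MRTF lists were chosen after the gene results had been seen, though before their own tests, and the tests over splits at an adjusted and at an unadjusted p, the comparison of neighbour windows between splits, and the value without ACTG1, were chosen after their results had been seen. A list of 30 measured targets of NRF2, the transcription factor of the oxidative stress response, was drawn up after AKR1C1, AKR1C2 and AKR1C3, which it leaves out, had been found among the most different genes. Of these targets 22 were higher in EP300 cultures, with a median of 0.2 ± 0.08 (SE of the median) and a camera p of 1.26e-04, or 2.52e-04 adjusted over the 2 lists tested in this part. With an estimated correlation p = 0.0121. At an unadjusted limma p below 0.05, 6 members were higher and 0 lower. They were the cystine transporter gene SLC7A11 (0.83 ± 0.20 SE), ME1 (0.75 ± 0.22), PRDX1 (0.76 ± 0.23), NQO1 (0.71 ± 0.22), CBR1 (0.63 ± 0.21) and TXNRD1 (0.57 ± 0.21), none of which passed the adjustment over all probe sets. Of other genes that this factor is known to control, HMOX1 was near 0 (0.0005 ± 0.22, counted among the 22), and GCLM (-0.26 ± 0.21) and GCLC (-0.37 ± 0.24) were on the lower side without passing.

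The higher AKR1C values are consistent with a hypothesis of a broader NRF2 response, by the median of 0.2 for the other targets. The NRF2 list stayed higher without any 1 array (camera p from 1.92e-04 to 0.00241), its lowest camera p in the other 9 splits was 0.0545, and 10 of 10000 lists matched on level had as high a median. A copy gain of the surrounding chromosome 10 segment was argued against by the 33 nearest named genes outside the cluster, whose median was 0.0814 ± 0.0755 (SE). Some of these neighbours had low levels, such as ADARB2 (2.543) and AKR1E2 (2.919), and could hardly show a gain. The neighbours with a mean level above 10 were IDI1 (-0.67), PFKP (0.21), KLF6 (0.16), GDI2 (-0.009) and ATP5F1C (0.28), named after their values were seen. Of the cluster's other genes, AKR1C8 was at -0.46 ± 0.25 SE and AKR1C4 at -0.13 ± 0.33, named after their values were seen. Their mean levels of 3.85 and 3.53 are low, where the background is unknown, so a gain of the cluster alone stays open. Signal shared among the AKR1C probe sets stays open too, because the mean correlation of their deviations within groups was -0.149 with a standard error near 0.5. Whether EP300 or a difference between the transfected pools would stand behind this is untested.

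For the lower hypoxia and mesenchymal lists, a shift of highly expressed genes is argued against, since 0.05% of 10000 level-matched lists had as low a median as the hypoxia list and 0 had as low a median as the mesenchymal list. Dependence on 1 array is argued against as well, since the highest adjusted camera p of either list without 1 array was 0.0249. A general fall of targets of SRF and its MRTF co-factors, which include TAGLN and ACTA2, was tested on 25 targets outside the mesenchymal list. Their median was -0.0288 ± 0.109 (SE) with a camera p of 0.193. For the 24 left without ACTG1, which had 1 constant value, it was -0.0544 ± 0.114 with a camera p of 0.183. A general fall therefore stays undecided. At an unadjusted limma p below 0.05 there were ACTG2 (-1.003), TUFT1 (-1.31) and CFL1 (-0.54) on the lower side and FILIP1L (0.74) on the higher. The mean level of FILIP1L (3.313) lay below the lower quartile of each array, where the background is unknown. Cell density, oxygen supply at harvest and the effect of EP300 remain open and untested.

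The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probe sets past the threshold, as did all 10 splits. It gave 1399 probe sets at an unadjusted p below 0.05 and the highest other split 1126. It gave 4 camera lists, with 2 in the highest other split, and 16 lists in the fry test for either direction, with 1 in the highest other split. The hypoxia list had an unadjusted camera p of 1.47e-05 in the real split and 0.00278 at the lowest in another, and the mesenchymal list 9.69e-05 and 0.0194. Because both lists were singled out by their small p in the real split, this contrast is no further evidence. Of the 10 splits, 1, the real one, reached the real value in each of the 3 counts above 0.

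Copy number differences between the pools were tested by the medians of 576 windows of 30 neighbouring genes. Their mean absolute size was 0.0546, and 49 of 1000 shuffled gene orders gave as large a value, which met the bound of 5% set before the test. The comparison with other splits was made decisive only after that. There the ratio to shuffled orders was 1.047 for the real split and up to 1.079 for another, so copy number and effects of neighbouring genes within groups cannot be told apart here. The largest window median was -0.265, in a run of genes from ZNF101 to ZNF91 on chromosome 19 rich in zinc finger genes, and 36 of 1000 shuffles had a largest window of that size.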
